A study of Mus musculus with 5 samples.

How the data were processed

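RNA was measured in 5 libraries of mouse hair follicle stem cells (HFSCs), the slow-cycling epithelial cells of the follicle bulge. The cells were sorted from back skin in telogen, the resting phase of the hair cycle, as CD45-negative, integrin alpha 6-positive, CD34-positive and Sca-1-negative cells. Per the labels, 2 libraries came from control mice and 3 from mice with the genotype K15-CrePGR and Adrb2 flanked by loxP sites on both alleles, called Adrb2 cKO here. CrePGR is a Cre recombinase fused to a progesterone receptor domain that the drug RU486 switches on, and both groups received 4% RU486 in 10 treatments. The labels do not say whether control mice carried the transgene or the floxed allele. They also do not say that each library came from its own mouse, so p-values measure the spread between these libraries, part of which may be technical.

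Per the labels' protocols, 1 ng of total RNA per library was copied to cDNA with the SMART-Seq v4 kit and 10 PCR cycles, made into libraries with Nextera XT and sequenced on 2 flow cells as unpaired 75 bp reads, to at least 10 M reads per sample. This kit does not mark the strand of the RNA, so reads of a gene and of an overlapping antisense gene cannot be told apart. Full-length transcript kits of this type also read transcripts along their length, and a longer transcript collects more reads.

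The deposited table holds 31309 genes with 2 values per library. Per the file headers, the first is TPM, an estimate of transcript share that divides by transcript length and sums to the same total in each library. Per the file headers, the second is a normalized count, a per-gene signal on a scale shared by the libraries that is not whole numbers. Salmon, DESeq2 and the build mm10 are named in the submitters' processing notes, without versions or roles, and the annotation is not given in the sources used here. Across 9676 well measured genes the normalized count divided by the TPM was one constant per gene times one constant per library. Relative to control replicate 1, the library constant was 0.0089 in control replicate 2 and -0.4394, -0.8611 and -0.6076 in Adrb2 cKO replicates 1 to 3 on the log2 scale, with an SD across genes of at most 0.0022. The deposited normalized count and the deposited TPM therefore differ between libraries by scaling alone. Whole reads could not be recovered, since only 60.5 to 77.5% of low values lay within 0.1 of a whole multiple of one step, and no test on reads was run. Dividing the normalized count totals by the value of 1 read gave approximate depths of 10.95 and 10.7 M reads in the controls and 9.98, 9.17 and 9.77 M in Adrb2 cKO. No 2 libraries held identical values.

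Gene symbols, positions and transcript lengths came from GENCODE M21, whose build GRCm38 is the build mm10, and 31281 of the 31309 gene identifiers matched. Genes with at least 1 TPM in at least 2 libraries were tested, which left 14377. The test was limma-trend with robust variance shrinkage (limma 3.58.1 in R 4.3.3) on log2(TPM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with low TPM. With 2 libraries against 3 an exact two-sided permutation test of one gene cannot go below p = 0.2, so calls rest on limma's variance shared across genes. Gene lists were tested with camera at a preset correlation between genes of 0.01, for the 38 of 47 lists with at least 5 measured members, and again with an estimated correlation and with fry. The lists, the tests and the alternatives were written down before the data were examined, except for a TPM recomputed over nuclear protein-coding genes and a correction for transcript length and GC content, which were chosen after seeing the data.

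The rule for named genes was also fixed before the data were examined. It takes Adrb2, then the 10 largest rises and the 10 largest falls with an adjusted p below 0.05, no overlap between groups and a mean of at least 5 TPM in one group, leaving out unnamed gene models. It adds up to 4 members with the lowest p from each list described, and 12 genes of quiescence, the cell cycle and stem cell identity whatever their values. Genes chosen after their values were seen are said to be so.

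Alternatives to the test were other pseudocounts (0.1 and 5), no filter on low values, a mean of at least 5 TPM, 3 other scalings, the normalized counts, no variance trend, array weights, the replicate number as a block, and each library left out in turn. On values simulated for the comparison of Adrb2 cKO with control over the 14377 genes tested, the same fit recovered 66% of 50 genes raised by 2 on the log2 scale, 22% of 50 genes lowered by 2, and 4% of 50 genes raised by 1 and 4% of 50 lowered by 1. It made 4 false calls among 52, and no call where nothing had been changed. Genes with small changes were thus mostly missed in the simulation. The real comparison made 1809 calls against these 52, and more calls loosen the adjusted threshold. No shift of the median was simulated either, so these shares do not give the recovery of the real test. For gene models present in one group only, transcripts were aligned to those of the other genes in the table with blastn (BLAST+ 2.17.0). The tests of 3 patterns in the last section were designed after the data had been seen, and all but 3 of the 10 after their own tables were. A further 7 were run first and then dropped or replaced. They were the cell cycle median without either control library (at most -1.62 relative to all genes), upper follicle against suprabasal medians (difference -1.32, permutation p = 0.0163) and calls near Adrb2 (Fisher's exact p = 0.0655). The others were void. A model was summed with its closest copy (median size 0.889 over 22 models) or with copies of at most 4 times its TPM (0.485 over 11), although an abundant copy fixes such sums. The median of 472 intronic and antisense models (0.15, against 0.01 in matched lists) cannot stand for nuclear RNA without strand information. The gap between groups on chromosome 16 (1.67 on the log2 scale) followed from how the genes were chosen.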

Results

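Messenger RNA of sorted telogen hair follicle stem cells was profiled in 2 control and 3 Adrb2 cKO libraries to ask which transcripts change when these cells lose Adrb2, the beta-2 adrenergic receptor through which norepinephrine from sympathetic nerves can act on them. The approximate depth was 10.95 and 10.7 M reads in the controls and 9.98, 9.17 and 9.77 M in the cKO libraries, which limits precision for genes of a few TPM. Between 12441 and 12580 genes reached 1 TPM in the controls and between 13709 and 14342 in the cKO libraries. The 4 genes Gm24245, CT010467.1, Mir6236 and Lars2 held 17.1 and 14.9% of all TPM in the controls and 12.7, 8.21 and 7.72% in cKO replicates 1 to 3. In TPM recomputed over nuclear protein-coding genes, the median gene stood 0.49 higher in cKO on the log2 scale. Over all genes tested it stood 0.53 higher in the deposited TPM, against 0.01 in the normalized counts. Changes below are therefore also given relative to that median, and levels are mean TPM ± SD with n = 2 controls and n = 3 cKO libraries.

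Adrb2 itself was read first, as a check of the labels. Adrb2 (ENSMUSG00000045730, chromosome 18, 62177816 to 62179959 on the minus strand of mm10) stood at 9.21 and 7.07 TPM in the controls and at 1.22, 1.53 and 0.625 TPM in the 3 cKO libraries. The mean fell from 8.14 ± 1.52 to 1.13 ± 0.461 TPM, and the control mean was 7.22 times the cKO mean in TPM and 11.4 times in normalized counts. The log2 fold change was -2.12 (SE 0.35, limma adjusted p = 0.0179), and every cKO library lay below both controls. An exact permutation test gave a two-sided p of 0.2, the smallest that 2 against 3 libraries allow. The limma call was lost without control replicate 1 (adjusted p = 0.0932), without control replicate 2 (0.101), without cKO replicate 2 (0.0931) and with no filter on low values (0.154), while the fold change stayed between -2.29 and -1.94 with a library left out. Which part of the gene the loxP sites flank is not given in the sources used here, so remaining reads may come from outside the deleted part or from cells that kept the allele.

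Across all genes, 1613 of 14377 passed the test with higher TPM in cKO and 196 with lower TPM (limma, Benjamini-Hochberg adjusted p below 0.05), so 89.2% of the calls were higher. In normalized counts 546 passed higher and 956 lower, 36.4% higher, and 493 of the higher and 185 of the lower genes passed in both units. Under all 5 scalings tried, 86 genes were called higher and 102 lower, and these do not depend on how the libraries were scaled. The 2 groups did not overlap in 6601 genes (45.9%) in normalized counts, where chance gives 20%, and in 8256 (57.4%) in TPM, where the shift of the median separates groups by itself. Log2 values correlated across genes at a Pearson r of 0.937 to 0.961 within groups and 0.896 to 0.931 between groups. The first principal component, with 58.0% of the variance, set the 2 controls apart from the 3 cKO libraries. It was computed on TPM, so the shift of the median enters it too. Its scores were 22.6, 70.2 and 31.6 in cKO replicates 1 to 3, in the order of the sizes of their library constants. The number of calls rested on single libraries, with 16 genes passing without cKO replicate 2, 43 without control replicate 2 and 285 without control replicate 1. It was 3 with no filter on low values and 90 without both the variance trend and robust shrinkage.

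The genes that rose most by the fixed rule included nuclear long noncoding RNAs and neighbours on chromosome 16. Neat1, the RNA scaffold of nuclear paraspeckles, rose from 12.3 ± 0.681 to 100.4 ± 25.4 TPM (log2 fold change 2.90, SE 0.25, adjusted p = 0.00247), and Malat1, an abundant RNA of nuclear speckles, from 687 ± 162 to 4602 ± 1376 TPM (adjusted p = 0.00853). Angptl7, a secreted angiopoietin-like protein, rose from 35.9 ± 25.6 to 312 ± 58.9 TPM (adjusted p = 0.0204). Rnf165, a ubiquitin ligase, rose from 0.458 ± 0.456 to 9.65 ± 4.25 TPM. Dynlt1c, a dynein light chain with near-identical neighbouring copies that make its level uncertain, rose from 3.29 ± 0.1001 to 41.1 ± 10.52 TPM. Cfap298, linked to motile cilia, rose from 50.4 ± 15.5 to 336 ± 40.3 TPM, Eva1c from 11.7 ± 0.256 to 82.8 ± 22.8 TPM, and Synj1, a phosphoinositide phosphatase of vesicle recycling, from 1.54 ± 0.0864 to 19.9 ± 6.97 TPM. These 8 genes were called higher under all 5 scalings. The microRNA gene models Mir23b and Mir3097 completed the 10 largest rises, at 42.9 ± 17.9 against 1.97 ± 2.79 TPM and at 7.28 ± 5.58 TPM against controls listed at 0. Models this short are poorly measured by such libraries, and Mir3097 did not pass in normalized counts (adjusted p = 0.233).

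Eva1c, Cfap298 and Synj1 are neighbours on chromosome 16 between 90826719 and 91011308. The next protein-coding gene tested, Paxbp1 (91014037 to 91044543), named after its values were seen, also rose, from 4.02 ± 1.54 to 26.3 ± 10.99 TPM (log2 fold change 2.41, SE 0.38, adjusted p = 0.0166). The flanking genes Urb1 (0.08, adjusted p = 0.907) and Ifnar2 (0.39, adjusted p = 0.361) did not pass, but Ifnar1, farther out, did (1.25, adjusted p = 0.0400, and 0.0748 in normalized counts).

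**Figure D1:**
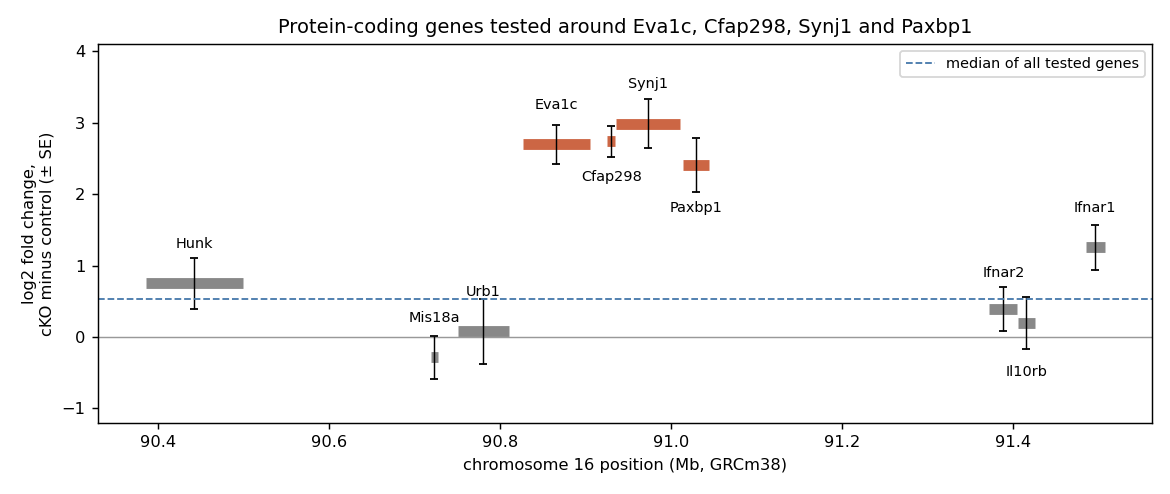
Log2 fold change of TPM (cKO minus control, limma estimate, error bars SE) of the 10 protein-coding genes tested around the run on chromosome 16, with each bar spanning the annotated gene along the x axis in Mb. The 4 genes of the run (orange) lie between 2.41 and 2.99 and their flanking genes (grey) between -0.29 and 1.25, with the median of all tested genes, 0.53, as a dashed line.

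The genes that fell most were mainly histones and genes of cell division. Ube2c, the ubiquitin-conjugating enzyme that drives exit from mitosis, fell from 134 ± 46.7 to 17.0 ± 14.6 TPM (log2 fold change -3.18, SE 0.70, adjusted p = 0.0454). Kifc1, a motor of the mitotic spindle, fell from 12.3 ± 1.46 to 0.992 ± 1.204 TPM (adjusted p = 0.0180), and Cenpm, a centromere protein, from 70.8 ± 29.6 to 10.9 ± 8.25 TPM (adjusted p = 0.0497). The histone genes Hist1h2ag, Hist1h2an and Hist1h3i fell to 0.226 ± 0.391, 0.837 ± 0.726 and 11.9 ± 10.6 TPM from 12.1 ± 3.02, 12.7 ± 10.1 and 93.1 ± 42.9 TPM. Hist1h4k and Hist1h2bl were listed at 0 in all 3 cKO libraries against 12.5 ± 3.12 and 5.14 ± 1.10 TPM in the controls. Histone genes have near-identical copies, so reads may have been divided among them and single members are uncertain. Hba-a2, an alpha globin chain of red blood cells, fell from 62.1 ± 31.5 to 7.33 ± 3.20 TPM, and Sprr4, a protein of the cornified envelope, from 7.89 ± 3.15 to 0.367 ± 0.635 TPM. In TPM and in normalized counts alike, these 10 genes passed as lower. Ube2c, Hist1h3i and Cenpm were not called under all 5 scalings, whereas the others were.

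The mitosis, DNA replication and histone lists had lower medians than any other list tested. The mitosis list (42 measured members) had a median 2.25 below that of all genes, with camera's adjusted p = 1.76e-31, which was 0.758 with an estimated correlation. Of its members 5 passed as lower and none as higher (19 lower and 1 higher adjusted over the list alone, and 15 lower in normalized counts). Kif2c, a spindle motor, fell from 4.87 ± 1.47 to 1.11 ± 0.503 TPM (adjusted p = 0.0401), Hmgb2, a chromatin protein of dividing cells, from 302 ± 26.8 to 168 ± 51.1 TPM, and Mki67, the proliferation marker Ki-67, from 6.54 ± 3.56 to 1.21 ± 1.10 TPM (adjusted p = 0.0464, and 0.0564 in normalized counts). The DNA replication list (40 members) had a median 1.48 below that of all genes (adjusted p = 8.64e-25, and 0.758 with an estimated correlation), and 10 members passed as lower (16 adjusted over the list alone, 24 in normalized counts). Mcm3, a subunit of the replicative helicase, fell from 26.6 ± 1.39 to 6.47 ± 0.726 TPM (log2 fold change -1.89, SE 0.27, adjusted p = 0.0163). Ung, which removes uracil from DNA, fell from 7.91 ± 0.928 to 0.716 ± 0.403 TPM, E2f1, a transcription factor of S-phase entry, from 6.78 ± 1.71 to 1.14 ± 0.623 TPM, and Hells, a chromatin remodeller, from 25.4 ± 3.25 to 8.66 ± 2.33 TPM. The list of histones and chromatin proteins (20 members) had a median 1.89 below that of all genes (adjusted p = 2.15e-20, and 0.758 with an estimated correlation), with 7 members lower (14 adjusted over the list alone, 12 in normalized counts). H2afz fell from 966 ± 339 to 319 ± 87.5 TPM, H2afx from 58.9 ± 12.4 to 19.7 ± 8.73 TPM, Hist1h4d from 139 ± 55.4 to 56.0 ± 10.8 TPM and Hist1h1a from 49.9 ± 28.8 to 8.20 ± 5.79 TPM. Taking the 3 lists as one set of 101 genes, 100 lay below the median of all genes, and the median difference stayed between -2.19 and -1.62 whichever library was left out.

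The list of G1 cyclins, their kinases and the E2F and RB proteins (22 members) had a median 0.29 below that of all genes (adjusted p = 0.0203, and 0.860 with an estimated correlation), and the call was lost under several scalings, without control replicate 2 (adjusted p = 0.0783) and without cKO replicate 1 (0.123). Its members passed in both directions, 2 higher and 3 lower (6 higher and 4 lower adjusted over the list alone, none higher and 6 lower in normalized counts). Ccne2, a cyclin of the G1/S transition, fell from 24.6 ± 15 to 5.96 ± 2.58 TPM and Cdk4 from 590 ± 90.2 to 383 ± 52.0 TPM, while Rb1, a brake on S-phase entry, rose from 13.8 ± 2.53 to 32.8 ± 8.43 TPM (adjusted p = 0.0404, and 0.185 in normalized counts). Ccnd1 stood at 69.3 ± 6.42 and 95.1 ± 20.9 TPM and did not pass (adjusted p = 0.202). It was 0.10 below the median of all genes in TPM and -0.21 in normalized counts.

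**Figure D2:**
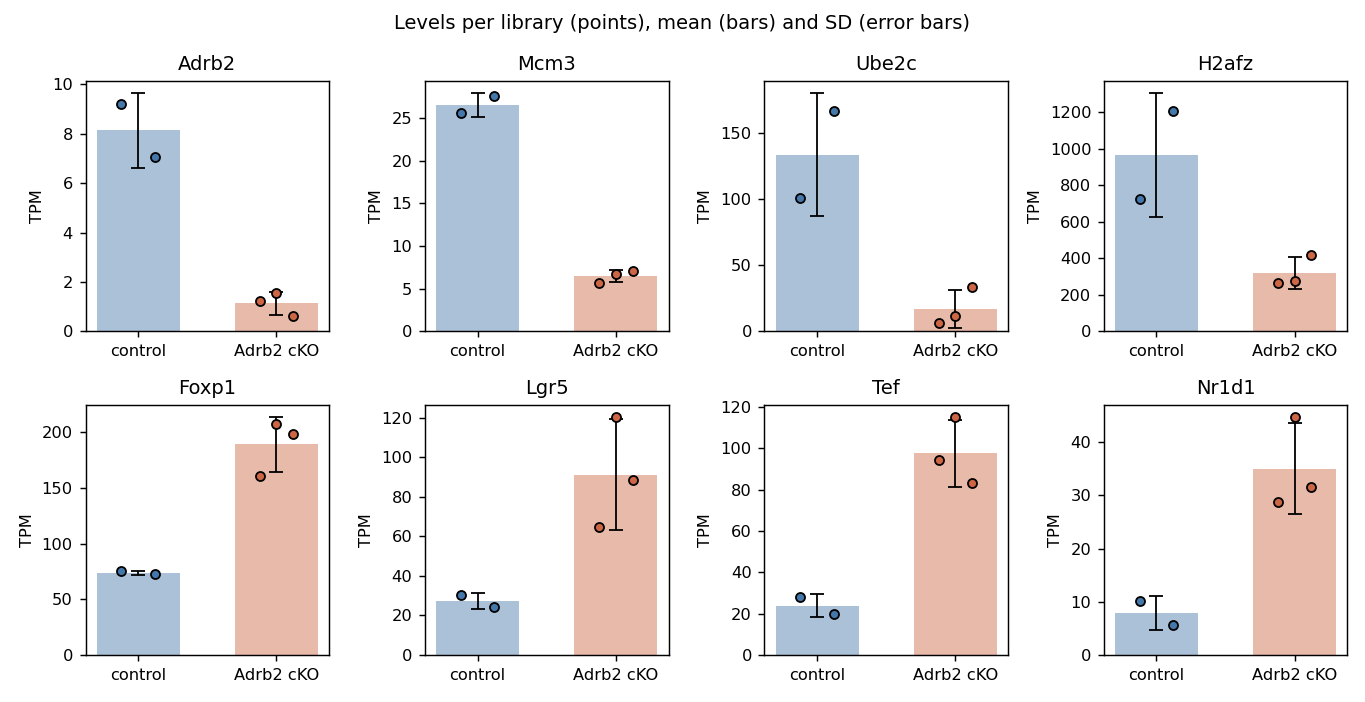
TPM of 8 genes in each library, with points for libraries, bars for the mean and error bars for the SD (n = 2 controls, n = 3 cKO). Adrb2, Mcm3, Ube2c and H2afz are lower in all 3 cKO libraries than in both controls, and Foxp1, Lgr5, Tef and Nr1d1 are higher, with Foxp1 at 73.7 ± 1.86 and 189 ± 24.9 TPM.

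Genes of ribosomal proteins and nuclear-encoded genes of respiration were also lower relative to other genes. The cytosolic ribosomal proteins (49 members) had a median 0.81 below that of all genes (camera adjusted p = 4.42e-27, and 0.758 with an estimated correlation), with 8 members lower (18 adjusted over the list alone, 38 in normalized counts). Rpl15 fell from 984 ± 19.7 to 613 ± 53.8 TPM, Rpl6 from 1583 ± 100 to 1064 ± 107 TPM, Rps2 from 2477 ± 158 to 1720 ± 127 TPM and Rps11 from 2610 ± 56.6 to 1846 ± 106 TPM. The nuclear genes of oxidative phosphorylation (55 members) had a median 0.83 below that of all genes (adjusted p = 2.67e-21, and 0.758 with an estimated correlation), with 7 lower and 1 higher (20 lower and 2 higher adjusted over the list alone, 36 lower in normalized counts). Cox5a, a subunit of cytochrome c oxidase, fell from 399 ± 35.6 to 221 ± 16.3 TPM (log2 fold change -0.85, SE 0.15, adjusted p = 0.0203), as did Atp5e from 866 ± 155 to 499 ± 66.8 TPM, Atp5g1 from 1009 ± 70.1 to 649 ± 35.5 TPM and Cox7c from 748 ± 85.8 to 484 ± 27.2 TPM. The 13 mitochondrially encoded transcripts, which also serve respiration, did not pass as a list (median 0.15 below that of all genes, adjusted p = 0.846). None of them passed over all genes or adjusted over the list alone, with 1 lower in normalized counts. The ribosomal and nuclear-encoded respiration transcripts are short, and short protein-coding genes were lower as a class. The median change relative to all genes was -0.54 in the decile of the shortest protein-coding genes and 0.22 in that of the longest. Lists of random genes matched to both sets on length and mean TPM had a median of -0.58, with 95% of them between -0.69 and -0.47, against -0.82 for the 104 ribosomal and respiration genes together. A correction for length and GC content, chosen after the data were seen, left the medians at -0.69 for ribosomal proteins (adjusted p = 3.63e-18) and -0.65 for oxidative phosphorylation (1.31e-17). The list of MYC targets and ribosome biogenesis (33 members) had a median 0.44 below that of all genes (adjusted p = 0.0138, and 0.860 with an estimated correlation). Of its members 1 passed as higher and 2 as lower (none adjusted over the list alone, 4 lower in normalized counts), and without control replicate 2 the list's adjusted p was 0.237. Hspe1, a mitochondrial chaperone, fell from 244 ± 38.5 to 140 ± 15.2 TPM and Odc1, the first enzyme of polyamine synthesis, rose from 42.5 ± 19.9 to 102 ± 26.0 TPM (adjusted p = 0.0397, and 0.164 in normalized counts). Of the cholesterol synthesis list (24 members, median 0.54 below that of all genes, adjusted p = 6.34e-06, and 0.758 with an estimated correlation), 2 members passed as lower (2 adjusted over the list alone, 9 in normalized counts). Fdps, which makes farnesyl diphosphate, fell from 142 ± 14.7 to 49.6 ± 1.79 TPM (adjusted p = 0.00974) and Dhcr24 from 11.5 ± 0.754 to 3.70 ± 0.646 TPM (adjusted p = 0.0285). Dhcr7 (17.4 ± 0.459 and 29.3 ± 2.01 TPM) and Lss (7.32 ± 2.04 and 15.1 ± 3.73 TPM) did not pass.

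**Figure D3:**
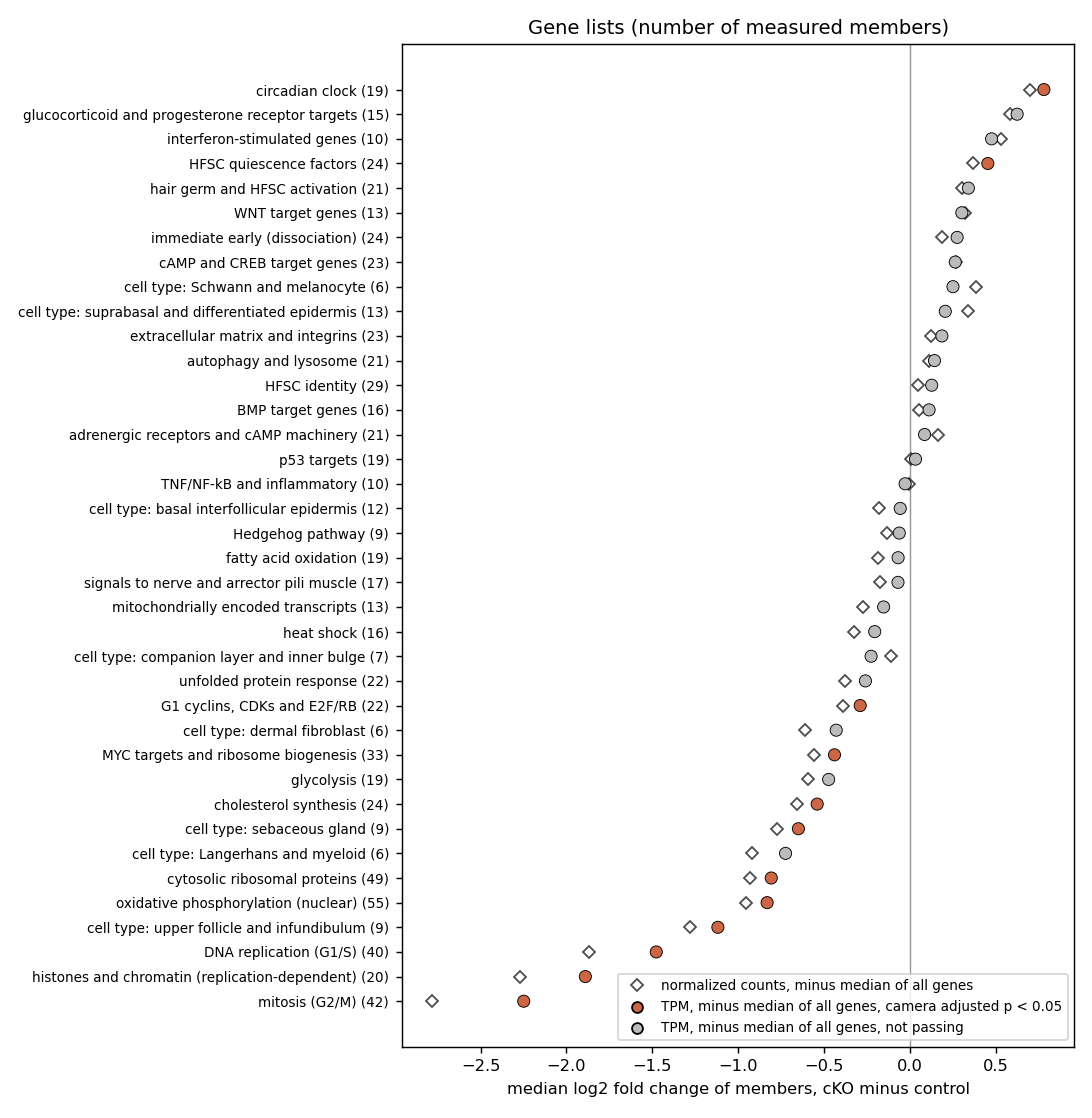
Median log2 fold change (cKO minus control) of the measured members of the 38 gene lists tested, minus the median of all tested genes, in TPM (circles, orange where camera's adjusted p was below 0.05) and in normalized counts (diamonds). The mitosis, histone and DNA replication lists lie farthest to the left, with mitosis at -2.25, and circadian clock genes farthest to the right at 0.78. No list passed with an estimated correlation, where the lowest adjusted p was 0.758, or with fry's test for change in one direction. In fry's test for change in either direction 31 passed.

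The circadian clock list (19 members) had the highest median of the lists tested, 0.78 above that of all genes (camera adjusted p = 0.00943, and 0.860 with an estimated correlation). Of its members 9 passed as higher and none as lower (12 higher adjusted over the list alone, 6 in normalized counts). Tef, a PAR-domain transcription factor, rose from 23.9 ± 5.72 to 97.6 ± 16.2 TPM (log2 fold change 1.99, SE 0.24, adjusted p = 0.00853) and was called under all 5 scalings. Nr1d1, the repressor REV-ERB alpha, rose from 7.85 ± 3.21 to 35.0 ± 8.58 TPM, Cry2 from 10.3 ± 3.23 to 34.6 ± 8.07 TPM and Per1 from 7.22 ± 1.01 to 20.8 ± 3.30 TPM. The labels give no time of day for tissue collection. The list's adjusted p was 0.0631 among genes with a mean of at least 5 TPM.

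The list of HFSC quiescence factors (24 members) had a median 0.45 above that of all genes (camera adjusted p = 0.0130, and 0.860 with an estimated correlation), with 11 members higher and none lower (14 higher and 1 lower adjusted over the list alone). In normalized counts 4 members were higher and 2 lower, and the list did not pass (adjusted p = 0.0713). It did not pass without control replicate 2 either (adjusted p = 0.148, median 0.15 above all genes). Foxp1, a forkhead factor that holds HFSCs in quiescence, rose from 73.7 ± 1.86 to 189 ± 24.9 TPM (log2 fold change 1.34, SE 0.18, adjusted p = 0.0141), which was 0.81 above the median of all genes (normalized counts 0.71, adjusted p = 0.0446). Prlr, the prolactin receptor, rose from 21.9 ± 1.195 to 62.0 ± 16.9 TPM and Lhx2, a transcription factor of the bulge, from 80.9 ± 22.2 to 222 ± 37.8 TPM. Fgf18, a secreted quiescence signal of the bulge, stood at 10.7 ± 7.96 and 25.2 ± 7.53 TPM and did not pass (adjusted p = 0.0877). Nfatc1 (35.0 ± 4.91 and 55.9 ± 9.85 TPM) and the cell cycle inhibitor Cdkn1b (12.7 ± 0.586 and 22.0 ± 6.47 TPM) did not pass either, and Bmp6 was too low to be tested.

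The list of HFSC identity genes (29 members) did not pass as a whole (adjusted p = 0.0722). It did pass as higher without control replicate 1 (0.00854, median 0.36 above all genes against 0.13 with all libraries and 0.01 without control replicate 2), with no filter (0.00118) and with quantile normalization (0.00173). Of its members 15 were higher and 1 lower in TPM (18 higher and 2 lower adjusted over the list alone), against 5 higher and 3 lower in normalized counts. Lgr5, a receptor that marks bulge and hair germ cells, rose from 27.3 ± 4.27 to 91.1 ± 28.1 TPM (log2 fold change 1.67, SE 0.28, adjusted p = 0.0180, normalized counts 1.06). Col17a1, a hemidesmosomal collagen, rose from 268 ± 85.8 to 746 ± 163 TPM and Sox9 from 88.1 ± 7.55 to 158 ± 21.01 TPM, but neither passed in normalized counts (adjusted p = 0.0599 and 0.558). Cd34, a surface protein used for the sort, stood at 205 ± 46.1 and 435 ± 90.8 TPM (adjusted p = 0.0250, normalized counts 0.215). Krt15, the bulge keratin whose promoter drives the transgene, was at 8671 ± 98.6 and 11930 ± 862 TPM, and its direction depended on the scaling. It passed as higher in TPM (0.46, adjusted p = 0.0285) and did not pass at -0.18 in normalized counts, -0.14 with TMM scaling and -0.15 with median-of-ratios scaling. The hair germ and activation list (21 members, adjusted p = 0.338) passed with no filter alone (0.0495) and held 6 members higher and none lower (11 higher and 1 lower adjusted over the list alone, and 1 higher and 2 lower in normalized counts). They included Nog, a BMP antagonist (6.25 ± 0.902 to 26.3 ± 5.76 TPM, also called in normalized counts), and Lef1, Alcam and Msx2, which passed in TPM alone.

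Lists of genes that read out or carry adrenergic signals did not pass against other genes, although both passed fry's test for change in either direction (adjusted p = 0.0238 and 0.0239). The cAMP and CREB target list (23 members) had a camera adjusted p of 0.762 and a median of 0.75 and -0.36 relative to all genes without control replicates 1 and 2, with 2 members higher and none lower (2 higher adjusted over the list alone, 1 higher and 1 lower in normalized counts). These were Per1, given above, and Rgs2, a regulator of G protein signalling, which rose from 17.4 ± 1.35 to 41.3 ± 0.856 TPM (adjusted p = 0.0219, and 0.137 in normalized counts). The list of adrenergic receptors and cAMP machinery, which leaves out Adrb2 (21 members, adjusted p = 0.619), held 3 members higher (4 adjusted over the list alone, 1 higher and 1 lower in normalized counts). Adra2c, an alpha-2 adrenergic receptor, rose from 0.517 ± 0.238 to 2.96 ± 0.450 TPM (adjusted p = 0.0399, and 0.0481 in normalized counts). Adcy3, an adenylate cyclase, and Prkacb, a catalytic subunit of protein kinase A, rose in TPM but did not pass in normalized counts (adjusted p = 0.0691 and 0.0927).

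Markers of other skin cells were read to see what else the sort could hold. The upper follicle list (9 members) had a median 1.12 below that of all genes (camera adjusted p = 0.00136, and 0.860 with an estimated correlation). Its adjusted p was 0.0577 with quantile normalization. None of its members passed in TPM, 5 were lower in normalized counts, and 2 were higher and 4 lower adjusted over the list alone. Defb6, a defensin of the upper follicle, stood at 305 ± 31.8 and 80.4 ± 47.3 TPM and Klk10 at 6.36 ± 1.29 and 2.06 ± 0.989 TPM, while Plet1 stood at 11.9 ± 1.59 and 30.0 ± 12.6 TPM. The sebaceous gland list (9 members) had a median 0.65 below that of all genes (adjusted p = 0.0388, and 0.758 with an estimated correlation), with no member passing over all genes or adjusted over the list alone and 2 lower in normalized counts. It was lost under most alternatives (adjusted p = 0.0834 in normalized counts). Elovl3 stood at 2.26 ± 0.170 and 0.893 ± 0.528 TPM and Fabp5 at 58.5 ± 7.32 and 46.6 ± 10.8 TPM. The suprabasal epidermis list (13 members) had a median 0.21 above that of all genes, although camera's direction was lower, and did not pass (adjusted p = 0.619). None of its members passed in TPM or adjusted over the list alone, and 2 were lower in normalized counts. The basal interfollicular epidermis list (12 members, adjusted p = 0.639) held 4 members higher and none lower (4 higher adjusted over the list alone, 1 in normalized counts), namely Itgb4, Thbs1, Tgfbi and Ptn. In TPM, 1 member of the companion layer list (7 members, adjusted p = 0.651), Krt6a, and 1 of the fibroblast list (6 members, adjusted p = 0.754), Sparc, passed as higher (1 each adjusted over the list alone). Neither passed in normalized counts, where 1 companion layer member was lower. Of the red blood cell list only Hba-a1 and Hba-a2 were measured, and both fell, with Hba-a1 at 31.6 ± 4.59 and 8.73 ± 1.98 TPM.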

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

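The length and GC correction and the TPM recomputed over protein-coding genes were chosen after the data were seen. The edgeR and DESeq2 alternatives on recovered reads were not run because whole reads could not be recovered from the deposited values. The number of genes changed in Adrb2 cKO against control was the least stable result. Against 1809 genes (1613 higher, 196 lower), 3 passed with no filter on low values (2 higher, 1 lower), 972 with TMM scaling (306 and 666), 831 with median-of-ratios scaling (273 and 558), 277 with quantile normalization (131 and 146), 90 without trend and robust shrinkage (71 and 19), 3454 with array weights (3082 and 372), 1502 in normalized counts (546 and 956) and 776 with the length and GC correction (247 and 529). The protein-coding TPM called 2200 higher and 359 lower. Leaving out 1 library gave 16 to 2960 calls (12 to 2661 higher, 4 to 299 lower), with 16 without cKO replicate 2, 43 without control replicate 2, 285 without control replicate 1 and 2960 without cKO replicate 1. Where an arm keeps 1 control, that library is assumed to vary like the cKO libraries. The cause of these differences was not tested. The fits that leave one library out hold fewer samples, but the calls rose to 2960 without cKO replicate 1. The scalings gave 31.5 to 47.3% of calls as higher, against 89.2% in TPM. Of the genes called higher in TPM, 493 were shared with the normalized counts and 306 with TMM scaling, and of the lower genes 185 and 196.

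Of 93 named genes that passed, 87 kept their call with a pseudocount of 0.1, 84 with 5, 71 in normalized counts, 69 with TMM scaling, 44 with quantile normalization, 20 without trend and robust shrinkage and 1 with no filter. They kept it in 41 and 10 cases without control replicates 1 and 2, and in 86, 7 and 80 without cKO replicates 1, 2 and 3. Adrb2 kept its direction throughout, with -2.12 (adjusted p = 0.154) with no filter on low values and -2.29 to -1.94 with 1 library left out. Directions turned for Krt15 (-0.14 with TMM, -0.15 with median-of-ratios scaling, -0.18 in normalized counts), Ccnd1 (-0.16, -0.17 and -0.21, and -0.28 with the length and GC correction), and with that correction for Nfatc1 (-0.05), Cdkn1b (-0.06) and Ptn (-0.03, and -0.02 in normalized counts), all of which lie near the median shift of 0.53 in TPM. The uncalled flanking genes of the chromosome 16 run turned too. With TMM, median-of-ratios and quantile scaling, normalized counts and the length and GC correction, Ifnar2 was -0.17, -0.18, -0.22, -0.22 and -0.23 and Urb1 was -0.29, -0.3, -0.45, -0.4 and -0.48, and Urb1 ranged from -0.5 to 0.67 with a library left out. Gm24245, also uncalled, was 0 with quantile normalization. The list of mitochondrially encoded transcripts turned to 0.48 above all genes with quantile normalization and passed as higher there (adjusted p = 0.0135).

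Of 12 gene lists called, 0 passed with an estimated correlation and 0 with fry's test for change in one direction, while 10 passed fry's test for change in either direction. Neither fry test compares a list with other genes. The mitosis, DNA replication, histone, ribosomal protein, oxidative phosphorylation and cholesterol lists kept their call under every other alternative run, but not their size. With quantile normalization the ribosomal median went from -0.81 to -0.17 and that of oxidative phosphorylation from -0.83 to -0.21, and with no filter to -0.41 and -0.44. The difference between the mean correlation within and between groups, 0.0297, became 0.0179 with no filter and 0.044 with a mean of at least 5 TPM, and lay between 0.0199 and 0.0409 with a library left out. The groups share replicate numbers 1 and 2, but deviations of same-numbered libraries correlated at only 0.047 and -0.03. With 2 controls their deviations mirror each other, so both values rest on the same control difference. They cannot show whether the numbers pair libraries. With the replicate block 3 lists gained a call, among them HFSC identity (camera adjusted p = 0.0269) and extracellular matrix (0.0330), and 1 list lost its call. The replicate block gave 3676 calls (3121 higher and 555 lower). Only cKO replicate 3 holds number 3, so a block term of its own absorbs that library. The block's fold changes therefore rest on the other libraries, as in the fit without cKO replicate 3 (Adrb2 -1.94 in both). Fewer residual degrees of freedom per gene were left than in the main fit. At about 9 to 11 M reads, genes of a few TPM rest on few reads, and uncalled genes are not shown to be unchanged.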

Other observations

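The genes in this paragraph beyond the fixed lists were chosen after their values were seen. Both EPAC genes, which encode exchange factors that bind cAMP directly, rose in cKO. Rapgef4 (EPAC2) rose from 4.88 ± 1.25 to 32 ± 6.58 TPM (limma adjusted p = 0.00853, called under all 5 scalings) and Rapgef3 (EPAC1) from 0.403 ± 0.153 to 4.57 ± 0.318 TPM (adjusted p = 0.0174, and 0.0165 in normalized counts). Among the 86 genes called higher under all 5 scalings, Cxcl12, a chemokine, rose from 14.7 ± 5.80 to 75.4 ± 21.7 TPM, Fgf1 from 5.27 ± 2.84 to 34.3 ± 9.72 TPM, Il31ra, a receptor chain for interleukin 31, from 30.0 ± 11.04 to 189 ± 66.3 TPM, and Chat, the enzyme that makes acetylcholine, from 7.41 ± 2.68 to 39.2 ± 8.46 TPM. Firre, a nuclear long noncoding RNA also called under all scalings, rose from 4.18 ± 1.12 to 25.3 ± 5.95 TPM.

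Among the fixed lists not described above, 15 targets of the glucocorticoid and progesterone receptors, which RU486 binds, had a median 0.63 above that of all genes without passing as a list (camera adjusted p = 0.138, but 0.0231 with no filter, 0.0339 with quantile normalization and 0.0263 without control replicate 1). Of these, 6 passed as higher and none as lower (9 higher and 1 lower adjusted over the list alone, 3 higher and 1 lower in normalized counts), among them Zbtb16 (8.18 ± 2.88 to 30.2 ± 7.52 TPM), Klf15 (5.70 ± 1.497 to 19.2 ± 3.13 TPM) and Tsc22d3 (52.1 ± 6.25 to 133 ± 30.5 TPM, adjusted p = 0.0596 in normalized counts). Of 10 interferon-stimulated genes (adjusted p = 0.127), Usp18 and Ifih1 passed as higher in TPM and in normalized counts (6 adjusted over the list alone). Of 23 genes of the extracellular matrix and integrins (adjusted p = 0.0520, but 0.0377 with a pseudocount of 5, 0.0340 with a mean of at least 5 TPM, 0.0339 with quantile normalization, 0.00597 with no filter and 0.00854 without control replicate 1), 8 passed as higher (13 adjusted over the list alone), including the hemidesmosome and laminin genes Itgb4 (33.5 ± 1.15 to 80.5 ± 13.3 TPM) and Lamb3 (60.5 ± 4.37 to 157 ± 27.4 TPM), which did not pass in normalized counts. In normalized counts 3 members were higher, among them Thbs1, and 1 lower. The glycolysis list (19 members) had a median 0.47 below that of all genes and did not pass in TPM (camera adjusted p = 0.105). It passed as lower in normalized counts (0.0204), with 1 member higher and 4 lower there. In TPM 3 of its members were higher and none lower (4 higher and 2 lower adjusted over the list alone).

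In the 3 patterns below, both tests of transcript length and that of the share of models with a copy were set out before their results were seen, and the others after. The first pattern is that cell cycle, ribosomal and oxidative phosphorylation lists were lower in cKO. Transcript length alone argues poorly for either part, since the cell cycle median of -1.92 and the ribosomal and respiration median of -0.82 each lay at percentile 0 of 10000 lists matched on length and mean TPM, although length takes up part of the second, whose matched median was -0.58, while the length and GC correction left -0.69 for ribosomal proteins and -0.65 for oxidative phosphorylation. If a larger share of nuclear RNA in the cKO libraries lowered cytoplasmic messages alike, both sets would fall by the same amount. The cell cycle genes stood -1.10 on the log2 scale against the ribosomal and respiration genes (permutation p over genes = 1e-04, the smallest possible). An equal fall was assumed, however, and protein-coding genes changed by -0.54 in the shortest decile and 0.22 in the longest. The gap thus argues only against an equal fall as the whole cause, and a part played by nuclear RNA in the cell cycle fall stays open. The permutation p and the percentiles above resample genes within the same libraries, so they do not measure the spread between libraries. They also treat genes as independent, although estimated correlations in these lists ran from 0.255 (ribosomal proteins) to 0.87 (mitosis). For the ribosomal and respiration genes a larger nuclear share stays open, as the nuclear RNAs Malat1, Neat1 and Firre rose under all 5 scalings, while mitochondrially encoded transcripts had a median of -0.153 (-0.35 to 0.15 with a library left out, and 0.48 with quantile normalization, where they passed as higher). Fewer upper follicle cells, which the sort for CD34-positive and Sca-1-negative cells is meant to remove, also stay open, since their markers had a median of -1.12 but went both ways (2 higher, among them Plet1, and 4 lower adjusted over the list alone), and so do fewer dividing stem cells after loss of Adrb2, as the untested biological reading.

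The second pattern is 31 gene models with at least 8 times more TPM in every library of one group than in any of the other, counting values under 0.5 TPM as 0.5, of which 21 were higher and 10 lower in cKO. Near-identical copies were found for 22 of them (71.0%), against 6.94% of genes matched on mean TPM (permutation p = 1e-04, the smallest possible). A copy is another gene with a transcript at least 95% identical over 80% of the model, even where it overlaps the model. Class was not matched, so it may account for the excess. The 31 models hold 12 pseudogenes, 9 small RNAs and 8 protein-coding genes, while 11501 of the 14377 genes tested are protein-coding. Gm28438, a nuclear copy on chromosome 1 (24612775 to 24613119) of part of the mitochondrial gene mt-Nd3, was listed at 0 in both controls and at 894, 746 and 1278 TPM in cKO, while mt-Nd3 had a change of -2.05 after median-of-ratios scaling and their sum one of -0.48. Whether reads moved between copies in the models as a set stays open, because among 9 models whose copies held at most 4 times their TPM the copies changed in the opposite direction to the model in 4 and in the same direction in 5 (exact sign test p = 1), leaving out Gm2436 and Gm2446, which are copies of one another. Overlapping annotations were not left out. Gm28006, among these 5, lies within the span of its copy Neat1 on chromosome 19. Gm27624, also among them, matched Tug1 on the same chromosome at 100% identity. Sharing between copies does not cover the 9 models without such a copy, among them Rapgef3, Synj1, Csgalnact1 and Mfsd2a, and strain variants in the copies were not tested.

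The third pattern is the run of Eva1c, Cfap298, Synj1 and Paxbp1 on chromosome 16. Random gene order is argued against by a permutation test, in which no shuffle of 10000 gave a window of 4 neighbouring genes with so high a lowest change (permutation p = 1e-04, the smallest possible). The window of 4 was set after the run had been seen, so this p overstates the case. In the same scan for lower genes, the models Gm10720, Gm10719, Gm10718 and Gm10717 formed a window with changes of -2.93 or below relative to all genes. That is larger in size than the run's lowest change of 1.88, so joint movement of neighbours was not confined to this locus. The lower window was not set against shuffles. Overlapping gene models are argued against by annotated spans that overlap in 0 pairs, but read-through or unannotated transcripts between these close neighbours were not examined. A haplotype, a gain of copies or a transgene at this locus and a response to the loss of Adrb2 all stay open and untested, since that needs DNA or reads. Adrb2 itself lies on chromosome 18, where 0 of 24 other protein-coding genes tested within 2 Mb of it were called.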
